A study of Homo sapiens with 13 samples.

How the data were processed

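Total RNA of human skin fibroblasts was labelled with biotin and hybridised to Affymetrix HG-U133 Plus 2.0 arrays, per the labels, 1 array per hour from 0 h to 12 h after synchronization (13 arrays). The design text speaks of a parallel time course, which was not analysed here. The deposited values are intensity on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. The values themselves show a common scaling, since the mean after trimming 2% of probe sets at each end was 149.975 to 149.976 on every array. MAS5 subtracts mismatch signal, which makes dim probe sets noisy. Detection calls were not used here.

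The table held 54675 probe sets. In the platform annotation 41091 had 1 gene symbol, 1801 several and 11721 none, and 62 were array controls. Symbols were checked through gene identifiers against a RefSeq table, which matched 41043. To keep donor details out, 63 probe sets were left out. Values were transformed to log2(signal + 16), so folds of dim genes are understated. Probe sets below the median of all probe sets (mean log2 of 5.10) were dropped, which kept 27307, and the probe set with the highest mean was taken for each gene, which left 12384 genes. Of these, 6202 had further probe sets past the filter.

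Tests were run with R 4.3.3 and limma 3.58.1. Each gene was fitted with a line over 0 h to 6 h and a line over 7 h to 12 h, both over all 13 arrays with 9 residual degrees of freedom (prior 3.57), since there was 1 array per hour. The median residual SD was 0.23 log2. A natural cubic spline with 4 degrees of freedom tested smooth change, and a cosine and sine with a 5 h period tested cycling, each with the suffix as a covariate. Calls had a Benjamini-Hochberg adjusted p under 0.05. The number of arrays limits the precision, with a median SE of 0.04 log2 per hour over 0 h to 6 h and 0.05 over 7 h to 12 h. Of 24 gene lists, 22 had at least 3 tested members and were tested with camera at a preset correlation of 0.01 and with an estimated correlation. The melanocyte list kept 2 members (MITF and MC1R, of which 1 fell over 0 h to 6 h) and the immune list 2 (CD79A and CSF1R, of which 0 changed), too few to test. Cycling of 5 lists was tested with 100000 permutations of residuals across hours. Differences between single arrays were set against 10000 random lists matched on expression. These were drawn gene by gene and do not keep the correlation within a list. Figures were drawn with matplotlib 3.10.9.

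Lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls for each slope, 5 of each sign for the slope difference, the 10 smallest p for cycling where fewer passed, the 15 largest rises and 10 largest falls from 0 h to 1 h among brighter genes, up to 4 members of each list by size, and any tested Notch, Wnt, FGF or immediate early gene. Brighter genes had their brighter array of the pair at or above the median of tested genes. Alternatives covered scaling, the offset, the filter, probe sets, the variance prior, arrays left out, the suffix, the period and the spline. Simulated genes had flat means, independent noise with the spread left by the spline, and no early transient, so recovery in the real data may be lower. On these simulated data, slopes of 0.25 log2 per hour were recovered for 91% of changed genes over 0 h to 6 h and 67% over 7 h to 12 h. The smooth test recovered 64% of slow waves of 1 log2 but 0% of narrow waves, so brief pulses are not covered by it.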

Results

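RNA from cultured human skin fibroblasts was profiled each hour from 0 h to 12 h after synchronization, in a culture model of somitogenesis. Somitogenesis is the periodic formation of body segments in the embryo, in which genes of the Notch, Wnt and FGF pathways cycle. The series held 13 arrays, 1 per hour, from a single time course. The arrays of 0 h to 6 h carried one suffix in their titles and those of 7 h to 12 h another, of unstated meaning. No hour had a replicate array, so p-values measure scatter about fitted lines or curves, and differences between 2 single arrays carry no test. The arrays were closely matched in scale, with a trimmed mean signal of 149.975 to 149.976 and median signals of 19.9 to 23.1. The median of all probe sets lay below that of 0 h by up to 0.12 log2 (-0.12 at 9 h), and the counts of genes given for slopes and curves stayed within 1.5 times when each array was centred on its median. Fibroblast marker genes had a median signal of 4803, led by COL1A2 at 17041. Medians were 16.5 for keratinocyte markers, 15.7 for melanocyte markers, 9.12 for endothelial markers and 10.7 for immune markers. Somite and muscle markers had a median of 14.9, with 5 of 17 past the filter on dim probe sets and FOXC2 highest at 496. The keratinocyte list nevertheless held PERP, a junction gene, at a mean signal of 2797. After the filter on dim probe sets, 12384 genes were tested.

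The question of what changed directly after synchronization was addressed with the arrays of 0 h and 1 h. Immediate early genes, which are transcribed within minutes of stimulation, stood far higher at 1 h. ATF3 was 51.2-fold higher (log2 difference 5.68), NR4A1 34.1-fold (5.09), FOSB 27.2-fold (4.76) and EGR3 22.1-fold (4.47). Of 40 tested immediate early genes, 31 were at least 2-fold higher at 1 h and 0 at least 2-fold lower. Their median difference was 1.53 (SD over members 1.42), above all 10000 random lists of like expression. Their highest hour was 1 h for 20 genes and 2 h for 14. NR4A3 (4.40) and NR4A2 (4.31), nuclear receptors of the same family as NR4A1, stood higher as well. The BMP target genes ID3, ID1 and ID4, inhibitors of helix-loop-helix transcription factors, were higher by 4.95, 4.10 and 3.68. HES1, a Notch effector and core gene of the segmentation clock, was 13.2-fold higher at 1 h (3.72) while the median of the 22 tested Notch genes was 0.01. In the FGF list DUSP5, a MAP kinase phosphatase, differed by 3.49 and SNAI1 by 2.22. KLF10 (3.39), DLX2 (3.39), CXCL8 (4.14) and NFKBIA (3.38), an inhibitor of NF-kappaB, were also among the 15 largest differences upwards in genes whose brighter array lay at or above the median of tested genes. The signal of CXCL8 at 0 h (7.40) lay below the floor of the filter on dim probe sets (18.2), so its difference depends on the offset. Of 24 inflammatory and wound genes, 12 were at least 2-fold higher, with a median of 1.04, again above all random lists. Circadian genes had a median of 0.36, at percentile 99.99, with BHLHE40 at 2.97 and PER2 at 1.66. Medians were 0.28 for TGF-beta and BMP targets (percentile 100), 0.22 for quiescence genes (99.98), 0.18 for SRF targets (99.95), 0.08 for FGF genes (95.1) and 0.02 for Wnt genes (78.6). Random lists do not keep the correlation within a list, so a shift shared by its genes on 1 array can also give an extreme percentile. SCML2 (-1.14), ARHGAP22 (-0.96), TRIB2 (-0.95), TXNIP (-0.95), TCF3 (-0.92), PRDM1 (-0.91), SLC25A11 (-0.88), MT1HL1 (-0.87), DDIT4 (-0.85) and SDC1 (-0.80) had the largest differences downwards among genes whose brighter array lay at or above the median of tested genes. For ARHGAP22 and SLC25A11 the 1 other probe set of each past the filter differed in the opposite direction. Over all tested genes, 212 genes were at least 2-fold higher and 79 at least 2-fold lower at 1 h, against a median noise of 0.32 for a pair of arrays. The counts depended on the offset added before log2: with 64 they were 101 and 1, and with 1 they were 389 and 265. Among the differences of named genes, 19 values moved by more than the noise of a pair with quantile scaling or another offset. The 0 h and 1 h arrays had ACTB 3' to 5' signal ratios, a sign of RNA integrity, of 1.79 and 1.99, against 1.26 to 1.48 on the other arrays. The same ratio for GAPDH was 1.12 at 0 h and 1.17 at 1 h, against 0.971 to 1.14 on the other arrays, and did not set 0 h apart.

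**Figure D1:**
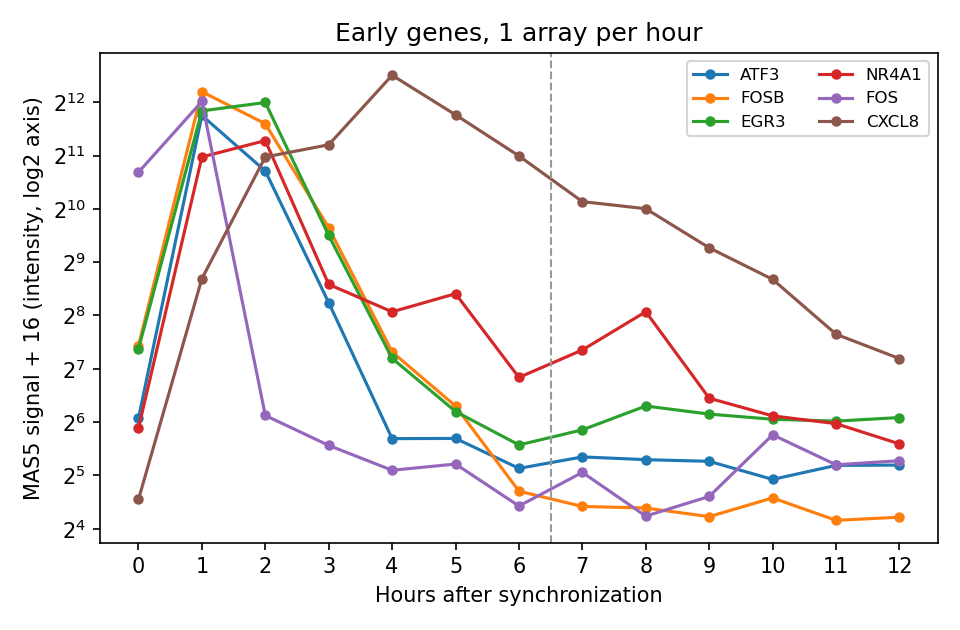
MAS5 signal plus 16 (intensity, log2 axis) of 6 early genes against hours after synchronization, with 1 array per point and a dashed line between the title suffixes. ATF3, FOSB and FOS were highest at 1 h, EGR3 and NR4A1 at 2 h, and CXCL8 at 4 h.

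Over 0 h to 6 h, the neutrophil chemokine CXCL8 rose by 0.96 ± 0.23 log2 per hour (slope ± SE over 7 arrays, adjusted p = 0.00839 in limma's moderated test). CXCL6 rose by 0.89 ± 0.09, TGFA, a ligand of the EGF receptor, by 0.85 ± 0.09, and CCL20 by 0.85 ± 0.10. TM4SF1 (0.79 ± 0.06), DIRAS3 (0.78 ± 0.08), HAS2 (0.77 ± 0.18), a hyaluronan synthase, SPHK1 (0.76 ± 0.11), IL11 (0.75 ± 0.19) and the hair keratin-associated gene KRTAP4-12 (0.88 ± 0.19) rose as well. FOS, an AP-1 subunit, fell by 1.19 ± 0.22 log2 per hour (adjusted p = 0.00186). FOSB fell by 0.87 ± 0.27, EGR3 by 0.77 ± 0.27, OSR2 by 0.85 ± 0.14, CSRNP3 by 0.85 ± 0.07 and TOX by 0.83 ± 0.10. TENT5C (-0.74 ± 0.05), SIM1 (-0.73 ± 0.08), GPSM2 (-0.69 ± 0.07) and TXNIP (-0.69 ± 0.16), a gene of glucose and redox control, also fell. The signals of CXCL8 (7.40), CXCL6 (1.25), TGFA (1.46), CCL20 (0.685) and KRTAP4-12 (2.70) at 0 h lay below the filter floor of 18.2, so the offset of 16 set the size and order of their slopes: with offset 64 these were 0.79, 0.58, 0.54, 0.50 and 0.55, and with offset 1 they were 1.13, 1.29, 1.25, 1.44 and 1.36, all still called. FOS (signal 5.49), FOSB and CSRNP3 lay below that floor at 6 h, and the slope of FOS was -0.91 with offset 64 and -1.45 with offset 1. EGR3 lost its call with offset 1 (slope -0.84, adjusted p = 0.0553 in limma's moderated test). In all, 3461 genes passed, 1356 rising and 2105 falling. Without the arrays of 0 h and 1 h, a setting chosen after seeing the data, 1067 passed. Without both arrays the calls of CXCL8 (slope 0.06, adjusted p = 0.83), IL11 (-0.11), HAS2 (0.15), KRTAP4-12 (0.42), FOS (-0.37), OSR2 (-0.41) and TXNIP (-0.08) were lost. Without the 1 h array alone, 2265 genes passed.

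Genes of ribosome production rose together over 0 h to 6 h, a window that includes the 2 arrays with higher ACTB 3' to 5' ratios. Of 21 tested ribosome biogenesis genes, 17 rose and 0 fell, both over all genes tested and adjusted over the list alone (camera adjusted p = 2.22e-10; adjusted p = 0.161 with an estimated correlation). RRP12 rose by 0.43 ± 0.06 log2 per hour, NOP16 by 0.41 ± 0.06, the helicase DDX21 by 0.39 ± 0.06 and NIP7 by 0.36 ± 0.05. Of 24 inflammatory and wound genes, 13 rose and 1 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 1.46e-07; adjusted p = 0.281 with an estimated correlation). Of 20 SRF and cytoskeleton genes, 9 rose and 1 fell, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.000325; adjusted p = 0.273 with an estimated correlation). Among them ACTG2, a smooth muscle actin, rose by 0.52 ± 0.08 and ENAH by 0.23 ± 0.04. Of 19 TGF-beta and BMP target genes, 5 rose and 1 fell on either adjustment, the same counts adjusted over the list alone (camera adjusted p = 0.0222; adjusted p = 0.441 with an estimated correlation). INHBA, an activin subunit, rose by 0.56 ± 0.08 and NOG, a BMP antagonist, by 0.37 ± 0.06. Without the arrays of 0 h and 1 h, the ribosome list still passed (camera adjusted p = 2.95e-06, and adjusted p = 0.182 with an estimated correlation). Its median slope was 0.14, against 0.19 with all arrays. The inflammatory list (median slope -0.04, camera adjusted p = 0.546), the SRF list (camera adjusted p = 0.388) and the TGF-beta and BMP list (median slope -0.09, camera adjusted p = 0.266) did not pass. The single ribosome genes named above lost their calls too, with fewer arrays in the fit.

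Over the same hours, 11 of 22 quiescence genes fell and 0 rose, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.000328; adjusted p = 0.214 with an estimated correlation). GAS1, named for growth arrest, fell by 0.67 ± 0.15 log2 per hour, CCNG2 by 0.56 ± 0.10 and the cyclin-dependent kinase inhibitor CDKN1C by 0.40 ± 0.07. Of 18 cholesterol synthesis genes, 11 fell and 0 rose, or 12 and 0 adjusted over the list alone (camera adjusted p = 0.00067; adjusted p = 0.273 with an estimated correlation). HMGCS1, an enzyme of the mevalonate pathway, fell by 0.61 ± 0.09, IDI1 by 0.36 ± 0.06 and SREBF1 by 0.22 ± 0.03. Of 24 G2/M genes, 11 fell and 0 rose on either adjustment, the same adjusted over the list alone (camera adjusted p = 0.0027, and adjusted p = 0.545 with an estimated correlation). CCNB2, a mitotic cyclin, was at -0.35 ± 0.06, but its 1 other probe set past the filter had a slope of the opposite sign. Of 15 interferon genes, 6 fell, also adjusted over the list alone (camera adjusted p = 0.025; adjusted p = 0.273 with an estimated correlation), with IFIT1 at -0.41 ± 0.06. Of 19 p53 target genes, 7 fell, or 9 adjusted over the list alone (camera adjusted p = 0.042; adjusted p = 0.545 with an estimated correlation), with TP53INP1 at -0.43 ± 0.08 and MDM2 at -0.30 ± 0.07. Of 22 lists tested, 9 passed and 0 did so with an estimated correlation. Without the arrays of 0 h and 1 h, the quiescence (adjusted p = 0.0016), cholesterol (1.28e-06) and p53 (0.00705) lists still passed. The G2/M list (median slope -0.10 against -0.17 with all arrays, adjusted p = 0.246) and the interferon list (-0.08 against -0.07, adjusted p = 0.072) did not, although the interferon slope was no smaller. With an estimated correlation those that passed were lost (adjusted p = 0.0999 for quiescence and cholesterol and 0.542 for p53 with an estimated correlation). In that setting the immediate early list fell (median slope -0.36, adjusted p = 7.79e-22; adjusted p = 0.0104 with an estimated correlation). The FGF list (-0.18, 0.000634), the Wnt list (-0.13, 0.0225) and the circadian list (-0.12, 0.0208) passed downwards at the preset correlation alone (adjusted p = 0.0999, 0.0999 and 0.166 with an estimated correlation).

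The remaining lists did not pass over 0 h to 6 h. Of 40 immediate early genes, 0 rose and 9 fell, or 0 and 8 adjusted over the list alone (camera adjusted p = 0.131). Of 16 circadian genes, 1 rose and 4 fell, or 2 and 4 adjusted over the list alone (0.471). Of 23 stress genes, 9 rose and 5 fell, or 10 and 5 adjusted over the list alone (0.0749). Of 5 keratinocyte markers, 1 rose and 1 fell, or 2 and 2 adjusted over the list alone (0.541). Counts were the same adjusted over the list alone for the next lists. Of 26 G1/S genes 1 rose and 6 fell (0.67). Of 27 extracellular matrix genes 5 rose and 0 fell (0.243), with a median slope of -0.02, a mean of 0.06 and an upward test. Of 23 hypoxia and glycolysis genes, 3 rose and 2 fell (0.356), with HK2, a hexokinase, rising by 0.35 ± 0.03. Of 5 somite and muscle genes 0 rose and 2 fell (0.23). Of 15 fibroblast markers 1 fell (0.227), and of 3 endothelial markers 1 rose (0.265). The FGF list had a median of 0.03, a mean of -0.07 and a downward test (0.583).

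Over 7 h to 12 h, ANLN, which acts in cytokinesis, rose by 0.54 ± 0.09 log2 per hour (adjusted p = 0.0281 in limma's moderated test, 6 arrays), and the kinetochore genes NDC80 and NUF2 by 0.54 ± 0.07 and 0.50 ± 0.07. HMMR (0.53 ± 0.09), MYBL1 (0.51 ± 0.08), OIP5 (0.49 ± 0.10), ASPM (0.47 ± 0.09), DEPDC1 (0.45 ± 0.09), ZWINT (0.45 ± 0.09) and RRM2 (0.47 ± 0.09), the ribonucleotide reductase subunit, rose as well. WWC1 fell by 0.46 ± 0.07, ADHFE1 by 0.39 ± 0.07, the collagen gene COL21A1 by 0.39 ± 0.07 and FLT1, a VEGF receptor, by 0.37 ± 0.07. ASAP2 (-0.35 ± 0.05), CHST2 (-0.35 ± 0.06), SECTM1 (-0.34 ± 0.05), PPL (-0.34 ± 0.07), FAM167A (-0.33 ± 0.05) and PPARD (-0.30 ± 0.05) also fell. The signals of WWC1 (5.785), ADHFE1 (3.794) and PPL (4.29) at 12 h lay below the filter floor of 18.2. So did those of NUF2 (9.768), OIP5 (14.43) and HMMR (17.7) at 7 h and DEPDC1 (5.119) at 8 h. The size and order of these slopes therefore depend on the offset of 16. In all, 88 genes passed, 52 rising and 36 falling. With limma, 0 genes passed without the 7 h array (1297 at an unadjusted p under 0.05), without the 8 h array (1452) or without the 12 h array (1114). With a step between 8 h and 9 h in the model, a setting chosen after seeing the data, 0 passed (1361 at an unadjusted p under 0.05).

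Both cell cycle lists moved together in this window. Of 26 G1/S genes, 3 rose over all genes tested and 22 rose adjusted over the list alone, with 0 falling (camera adjusted p = 9.73e-20; adjusted p = 0.268 with an estimated correlation). Of 24 G2/M genes, 3 rose over all genes and 23 adjusted over the list alone, with 0 falling (camera adjusted p = 1.2e-21; adjusted p = 0.268 with an estimated correlation). Slopes were 0.59 ± 0.16 for CDC45, a replication helicase factor, 0.50 ± 0.11 for MCM10, 0.74 ± 0.17 for the mitotic kinase CDK1 and 0.50 ± 0.13 for TOP2A. These slopes did not pass over all genes. Between 8 h and 9 h, 25 of 26 G1/S genes and 24 of 24 G2/M genes were higher. With a step there in the model, the G1/S list no longer passed (adjusted p = 0.323) and the G2/M list did (adjusted p = 0.000593; adjusted p = 0.694 with an estimated correlation). The median differences were 1.11 (SD over members 0.58) and 1.06 (SD 0.59), above all random lists. Both lists also lay above all random lists from 3 h to 4 h (0.50 and 0.57), 6 h to 7 h (0.85 and 0.41) and 11 h to 12 h (0.44 and 0.87), and at percentile 0 from 4 h to 5 h (-0.52 and -0.68). CDK1 differed by 2.95 between 8 h and 9 h, CDC45 by 2.54, CDC20 by 2.08 and MCM2 by 2.05. The stress gene DDIT4 differed by 3.13, while 16 of 19 p53 target genes were lower (median -0.41), as were 18 of 23 FGF genes (median -0.41). Of 18 cholesterol genes, 1 rose and 0 fell over all genes, and 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 8.75e-05; adjusted p = 0.28 with an estimated correlation). The gene that rose was SREBF1, a transcription factor of lipid synthesis, by 0.20 ± 0.04. Of 24 inflammatory and wound genes, 0 fell over all genes and 2 adjusted over the list alone (camera adjusted p = 1.46e-05; adjusted p = 0.597 with an estimated correlation), with PTGS2 at -0.60 ± 0.14. With the step, the inflammatory list did not pass (adjusted p = 0.138), the cholesterol list did (adjusted p = 0.0356), and the p53 list passed upwards (adjusted p = 0.0102). Both had an adjusted p = 0.694 with an estimated correlation.

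**Figure D2:**
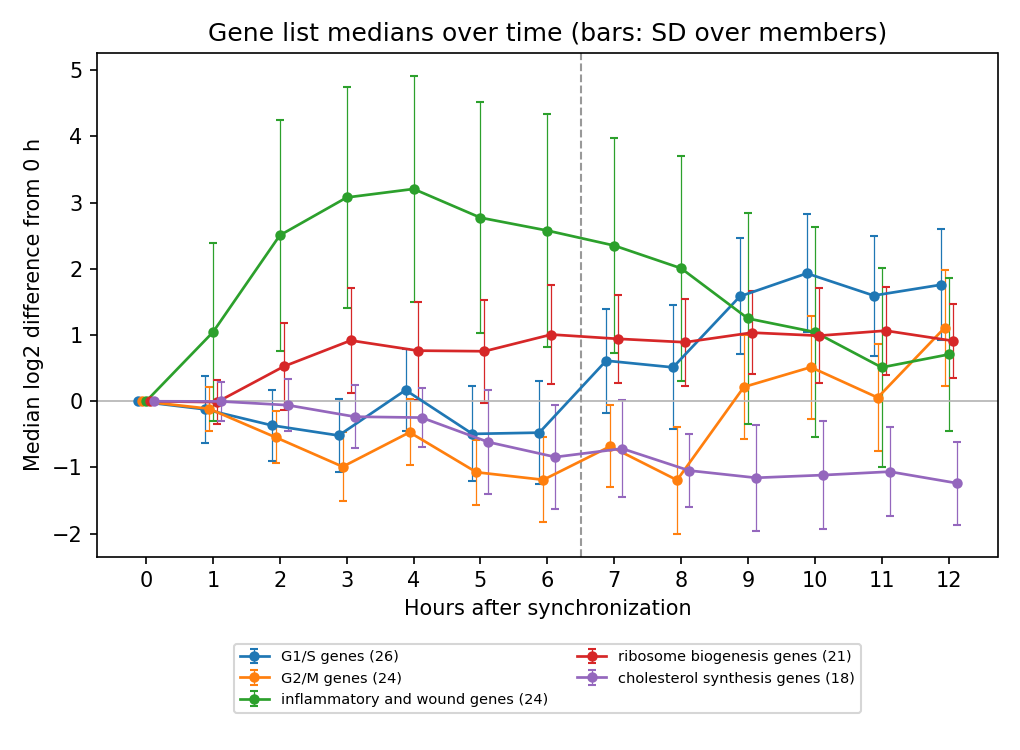
Median log2 difference from the 0 h array over the members of 5 gene lists against hours after synchronization, with bars for the SD over members, member numbers in parentheses and a dashed line between the title suffixes. The G1/S median was 0.51 at 8 h and 1.58 at 9 h, and the G2/M median -1.19 and 0.22.

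The slopes of the windows were compared directly. FOS had a slope of 0.15 ± 0.27 over 7 h to 12 h and a difference of 1.34 ± 0.35 (adjusted p = 0.0192 in limma's moderated test). OSR2 (1.21 ± 0.22), TXNIP (1.17 ± 0.25), the chromatin gene HMGB2 (1.10 ± 0.21) and TOX (1.06 ± 0.16) also differed upwards. CXCL8 (-1.60 ± 0.37), CCL20 (-1.32 ± 0.16), IL11 (-1.23 ± 0.30), TGFA (-1.17 ± 0.15) and SPHK1 (-1.16 ± 0.17) differed downwards. Without the arrays of 0 h and 1 h the calls of FOS (0.52, adjusted p = 0.0501), TXNIP (0.56, adjusted p = 0.117) and HMGB2 (0.81, adjusted p = 0.0828) were lost, and OSR2 (0.77), CXCL8 (-0.70), IL11 (-0.38) and SPHK1 (-0.71) kept theirs with smaller differences. The difference of CCL20 was -0.72 with offset 64 and -2.34 with offset 1. In all, 2291 genes passed, 1393 upwards and 898 downwards. As lists, G1/S (camera adjusted p = 5.85e-07; adjusted p = 0.401 with an estimated correlation), G2/M (1.3e-11; adjusted p = 0.332 with an estimated correlation), quiescence (0.00876; adjusted p = 0.332 with an estimated correlation) and interferon genes (0.016; adjusted p = 0.332 with an estimated correlation) differed upwards. Inflammatory (4.92e-09; adjusted p = 0.338 with an estimated correlation), ribosome (8.24e-08; adjusted p = 0.332 with an estimated correlation), SRF (0.00362; adjusted p = 0.401 with an estimated correlation) and TGF-beta and BMP genes (0.00876; adjusted p = 0.401 with an estimated correlation) differed downwards. The count was 1216 without the 7 h array, 932 without the 12 h array and 924 without those of 0 h and 1 h. Of the 88 genes called over 7 h to 12 h, 51 were also called over 0 h to 6 h, against 24.6 for independent lists (Fisher's exact test across genes, 2-sided p = 5.15e-09). Of these, 44 ran in opposite directions. Both windows shared an estimate of the spread, so genes with a low spread can pass more readily in both. Genes on the same arrays are also not independent, so the p-value of this overlap is too small.

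A step between the title suffixes, tested at 6.5 h, was found for 0 genes with limma (1049 at an unadjusted p under 0.05, smallest adjusted p = 0.26). On simulated data without other change over time, the test recovered 47% of steps of 1 log2 and 95% of steps of 2. A smooth change over 0 h to 12 h was found for 3208 genes by limma's moderated F test, with a median range of 1.43 log2. Of them, 1553 were highest at 0 h to 2 h, 716 at 3 h to 6 h and 939 at 7 h to 12 h. Without the suffix in the model 6412 passed, and without the arrays of 0 h and 1 h 580.

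Whether segmentation clock genes cycled was tested at a period of 5 h. No gene passed (0 of 12384 with limma's moderated F test, smallest adjusted p = 0.594), while 964 (7.78%) had an unadjusted p under 0.05. The FGF antagonist SPRY2 had an amplitude of 0.97 ± 0.18 log2 (adjusted p = 0.594 over all genes and 0.013 adjusted over the list alone), and SPRY4 an amplitude of 0.77 (adjusted p = 0.0428 over the list alone). Both were highest at 3 h. The SPRY2 signal then fell at every hour, from 4480 at 3 h to 572 at 10 h, without a second peak in that span. Of 23 FGF genes, 2 passed adjusted over the list alone and 0 over all genes. In the other lists 2 quiescence genes, 2 p53 targets, 1 interferon gene and 1 hypoxia gene passed adjusted over the list alone, and 0 in the rest. Of the 22 Notch and 22 Wnt genes tested, from lists of 35 and 30, 0 passed on either adjustment, the list alone included. HES1 had an amplitude of 0.64 ± 0.36. VLDLR had the smallest p, with an amplitude of 0.46 ± 0.07, followed by PMS2P5 (0.41), TTBK1 (0.59), BRI3BP (0.45), NCR3LG1 (0.57) and PATZ1 (0.47), none of which passed. FBXO30 (0.46), TMEM95 (0.58) and ATP8B3 (0.62) completed the 10 smallest, with SPRY2. As whole lists, the share of residual variance at 5 h was 31.03% for FGF genes against a permuted median of 19.0% (one-sided permutation p = 0.072, adjusted p = 0.249). It was 19.9% for Notch genes (permutation p = 0.482), 21.5% for Wnt genes (permutation p = 0.36), 27.4% for circadian genes (permutation p = 0.15) and 30.4% for immediate early genes (permutation p = 0.123), and no list passed after adjustment. At a period of 8 h the Wnt list did, with 41.6% of residual variance (permutation test, adjusted p = 0.00975, against 0.45 to 0.998 in its other settings). That adjustment covered the 5 lists at this period and not the other periods tried, and 12 h do not hold a second full cycle of 8 h. On simulated data with flat means, independent noise and no early transient, the gene test recovered 71% of cycles of amplitude 0.5 and 99% of amplitude 1. The real fits kept early changes beyond a linear trend in the residual, so these shares do not apply directly. SPRY2 at an amplitude of 0.97 did not pass over all genes.

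Several pathway genes changed with the slope over 0 h to 6 h instead. In the Notch list JAG1, a ligand, fell by 0.42 ± 0.07 log2 per hour and HES4 rose by 0.27 ± 0.05. Counts were 1 rising and 4 falling of 22, the same adjusted over the list alone. In the Wnt list 2 rose and 8 fell of 22, or 3 and 9 adjusted over the list alone, with AXIN2, a feedback inhibitor, falling by 0.46 ± 0.10 and TCF7L2 by 0.49 ± 0.07. TNFRSF19 fell by 0.45 ± 0.04 and then rose by 0.34 ± 0.05 over 7 h to 12 h (adjusted p = 0.0197 in limma's moderated test). Its 1 other probe set past the filter also fell over 0 h to 6 h but did not rise over 7 h to 12 h. Like all calls in that window, the late call of TNFRSF19 was lost without the 7 h, 8 h or 12 h array. In the FGF list 1 rose and 7 fell of 23, the same adjusted over the list alone, with EGR1 falling by 0.59 ± 0.11 and IL17RD by 0.32 ± 0.04. As lists, Notch (camera adjusted p = 0.353) and Wnt (camera adjusted p = 0.175) did not pass.

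**Figure D3:**
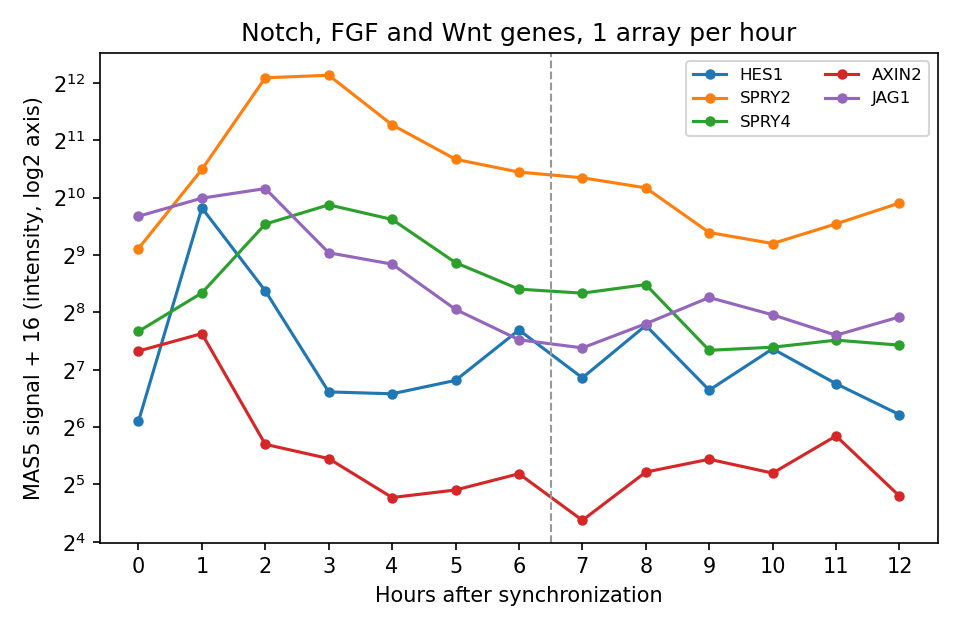
MAS5 signal plus 16 (intensity, log2 axis) of 5 Notch, FGF and Wnt pathway genes against hours after synchronization, with 1 array per point and a dashed line between the title suffixes. HES1 was highest at 1 h and SPRY2 and SPRY4 at 3 h, and none of the 5 passed the test for a 5 h cycle over all genes.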

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

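The tests of the 8 h to 9 h interval, the reading of the other periods as an explanation, the draws for the step and the settings without the 0 h and 1 h or the 0 h to 2 h arrays were chosen after the data were seen, although the periods and the step themselves were planned. The slope differed between 0 h to 6 h and 7 h to 12 h for 2291 genes by limma's moderated test of the difference itself. The differences were 1.34 log2 per hour for FOS, 1.21 for OSR2, 1.17 for TXNIP, 1.10 for HMGB2 and 1.06 for TOX. They were -1.60 for CXCL8, -1.32 for CCL20, -1.23 for IL11, -1.17 for TGFA and -1.16 for SPHK1. Without the 0 h and 1 h arrays they were 0.52 for FOS (adjusted p = 0.0501), 0.56 for TXNIP (adjusted p = 0.117) and 0.81 for HMGB2 (adjusted p = 0.0828), no longer called, and 0.77 for OSR2, -0.70 for CXCL8, -0.38 for IL11 and -0.71 for SPHK1, still called, and 924 genes passed in all. Outside the gene tests, 649 of 3914 probe sets without a single gene name also changed over 0 h to 6 h, 313 rising and 336 falling.

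Many more genes changed over 0 h to 6 h (3461) than over 7 h to 12 h (88). Unequal precision from the number of arrays is argued against. With 6 arrays on each side (median SE 0.053 in each window), the early count was still 28.0 times the late one. At an unadjusted p under 0.05 with limma it was 4183 against 1800. The late count of 88 over all arrays was 0 without the 7 h, 8 h or 12 h array. Both windows shared one estimate of the spread, so early departures from a line may have hidden late changes, which these counts cannot exclude. RNA quality of the 0 h and 1 h arrays, which stood apart in the ACTB ratio more than in that of GAPDH, is argued against as the whole cause, since 1067 genes were called without them and 98.3% of the called genes kept their sign over 2 h to 6 h, although those slopes share 5 arrays and 764 genes were called again. Among 100 orders of the hours within each suffix, 1 gave as many genes over 0 h to 6 h, the real one (3461, highest other 3001). It was also 1 of 100 for the slope over 7 h to 12 h (88, highest other 1) and the slope difference (2291, highest other 636). The same held for smooth change (3208, highest other 1285). A chance order of the hours as a whole is argued against for the 0 h to 6 h and smooth counts. Both windows were shuffled in the same draws and shared an estimate of the spread. Shuffled early hours could thus widen the spread and remove late calls, so these draws cannot decide on the order of the late arrays. Nor can they tell a drift over time from a biological response to synchronization, which stays open as a hypothesis.

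G1/S and G2/M genes stepped up together between 8 h and 9 h. A technical shift cannot be told apart. The 42 spike-in controls changed by a median of 0.12 log2, and the 18 of bioB, bioC, bioD and cre by 0.03. The 24 of dap, lys, phe and thr changed by 0.35 and were not uniform. The 18 of dap, lys and thr changed by 0.45 (0.10 to 0.99), but the 6 of phe by 0.07 (-0.02 to 0.25). A steady rise cannot be told apart either. The interval held 70.0% of the 8 h to 12 h rise. It also had the largest change of all, from a low value at 8 h, so this share decides nothing. Samples with different shares of dividing cells may contribute, if each hour was a separate dish, which the labels do not state: over the other 11 intervals the lists' median changes had r = 0.887 (permutation p = 0.00043; Spearman rho = 0.9, permutation p = 0.00019), above 99.93% of random pairs of lists (1 relation computed), and 0.95 without the 2 intervals farthest from the median, but neighbouring intervals share an array, so these p-values are too small. Cell cycle entry would also move both lists and stays open, untested with 1 array per hour.

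More genes than 5% had an unadjusted p under 0.05 at a 5 h period (964, or 7.78%), with 0 called. Chance order cannot be excluded, since 26 of 100 orders of the hours gave as many, the highest of the others 2902. The early transient may contribute. Without the arrays of 0 h to 2 h, a setting chosen after the data were seen, the share was 6.39%. This lay between the bounds of the test, so the transient cannot be told apart from other causes. Other periods gave 0 called genes with limma, with 202 (2.5 h) to 1313 (8 h) at an unadjusted p under 0.05. The Wnt list passed at 8 h (41.6% of residual variance, permutation test, adjusted p = 0.00975, against 0.45 to 0.998 in its other settings). Its adjustment covered the lists at that period and not the other periods tried. For the step between suffixes, 100 of 100 draws of 7 against 6 arrays gave at least the 0 genes of the real split, which a count of 0 makes certain, so the draws decide nothing about chance. The highest draw gave 2247, which points to a structure of the samples in a fit with 1 common slope in time, and its source was not tested.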

How the results depend on the processing

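Settings that leave out the 0 h and 1 h arrays together or the 0 h to 2 h arrays, or add a step between 8 h and 9 h, were chosen after the data were seen. No paired analysis was possible because all hours share only replicate number 1. For the main counts, quantile scaling and centring each array on its median stayed within 1.5 times, although array medians lay up to -0.12 log2 from that of 0 h. The slope over 0 h to 6 h gave 3461 genes, 6016 probe sets when every probe set was tested, and 1067 without the arrays of 0 h and 1 h (fewer arrays). The slope over 7 h to 12 h gave 88 genes, 213 with offset 64, 10 with no filter, 140 with a stricter filter on dim probe sets, 161 with an intensity trend, 41 with every probe set and 0 with the step. The slope difference gave 2291, 3690 with every probe set and 924 without the arrays of 0 h and 1 h. Smooth change gave 3208, 1952 with no filter, 4831 with every probe set, 6412 without the suffix and 580 without the arrays of 0 h and 1 h. The genes at least 2-fold apart at 1 h numbered 291, 102 with offset 64 and 654 with offset 1. Gene lists called fell from 9 and 4 to 0 and 0 with an estimated correlation. Over 0 h to 6 h, 7 lists passed with offset 1 and 7 with the stricter filter, with 3 falling in each against 5 in the main fit. With no filter, or with an intensity trend, 10 lists passed. The Wnt list passed at a period of 8 h (41.6% of residual variance, permutation test, adjusted p = 0.00975 over the lists at that period alone). It did not pass at 5 h or in its other settings (permutation test, adjusted p = 0.45 to 0.998). Other causes were not tested. Leaving out 1 array gave 2265 (without 1 h) to 3564 genes over 0 h to 6 h, 0 to 101 over 7 h to 12 h (0 without 7 h, 8 h or 12 h, and 42 to 54 without 1 h, 2 h, 5 h, 10 h or 11 h), 932 to 2412 for the difference (932 without 12 h, 1216 without 7 h), 1882 to 3357 for smooth change (1882 without 6 h, 1905 without 1 h, 2038 without 5 h, 2130 without 0 h), 0 to 1 for the step (1 without 6 h), 0 for the 5 h cycle, and 8 to 9 and 4 to 5 lists. Of 107 named genes, 17 changed the sign of the slope over 0 h to 6 h without the arrays of 0 h and 1 h, 12 of them called in neither setting. The 5 called in either were DDIT4 (0.031), ID4 (-0.48), IL11 (-0.11), PTGS2 (-0.037) and SPRY2 (-0.48). Leaving out 1 array moved the slope of DUSP5 from -0.30 to 0.29, that of ID4 from -0.33 to 0.26 and the slope difference of NFKBIA from -0.20 to 0.33, each turned by leaving out 0 h. Over 121 named genes, 3394 other values were called in both settings or in neither, or for 0 h to 1 h stayed within the noise of a pair of arrays. Values called in neither setting counted here even where their sign changed. Another 226 lost the call, 51 gained it, 19 moved beyond that noise and 8 were reversed, those given above for the 5 genes and for DUSP5, ID4 and NFKBIA. Dim genes are limited by signal over background, as the effect of the offset shows.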

Other observations

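The tests of HES1 and of the 8 h array were chosen after the values were seen. Some circadian and developmental genes not described above changed over 0 h to 6 h in limma's moderated test. The clock repressor NR1D2 fell by 0.52 ± 0.07 log2 per hour (adjusted p = 0.000373), RORA by 0.47 ± 0.07 and DBP by 0.31 ± 0.08. The homeobox gene MEOX2, of the somite list, fell by 0.53 ± 0.08 and the fibroblast marker TWIST1 by 0.30 ± 0.04. Of these, DBP and MEOX2 lost the call without the arrays of 0 h and 1 h (adjusted p = 0.0974 and 0.0853).

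HES1 alternated from hour to hour over 5 h to 12 h, by 0.30 log2 around its trend, more than 99.91% of 2203 genes of like level. HES1 was picked because it alternated, so that percentile decides nothing. A hypothesis of a 2 h alternation shared by the Notch list was tested on the 21 other members. Their median contrast was 0.05 log2, at percentile 71.5 of random lists, and 9 of 21 had the sign of HES1, which argues against it. Hourly sampling is too sparse to resolve a 2 h rhythm of HES1 alone.

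Genes at least 2-fold higher at 1 h stood above both neighbouring hours again at 8 h more often than in most random lists of like expression. The share was 36.8% of 212 genes, at percentile 99.22 of random lists (median 29.2%), with a median excess of 0.13 log2. At 4 h and 9 h the share was lower than in nearly all random lists (percentile 0.01 at each). A second rise was not shared by the immediate early and inflammatory lists. From 7 h to 8 h the immediate early and inflammatory lists had median changes of -0.10 and -0.18 (percentiles 2 and 0.7). From 8 h to 9 h they fell again, by medians of -0.20 and -0.36 (percentile 0 at each). The circadian and quiescence lists, also high at 1 h, did rise from 7 h to 8 h. Their medians were 0.21 and 0.12 (percentiles 99.25 and 97.46), and from 8 h to 9 h -0.05 and -0.12 (percentiles 21.7 and 3.57). For TGF-beta and BMP targets and SRF targets the medians from 7 h to 8 h were 0.02 and 0.003 (percentiles 68 and 60.5). For the 212 genes a second rise stays undecided. Their share did not exceed all random lists, 9 hours could have been picked, and 1 array cannot separate it from handling of that sample.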
